A study of Mus musculus with 19 samples.

How the data were processed

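Chromatin accessibility was measured by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into open DNA, in primary mouse bone marrow-derived macrophages. The labels describe 19 samples in 10 groups: wild-type or Smarca5-deleted cells, each untreated or given LPS at 10 ng/ml or interferon beta at 100 U/ml for 1 or 2 h. There were 9 wild-type and 10 deleted samples, with 2 samples in 9 groups and 1 sample in the wild-type group given interferon beta for 1 h. Samples were grouped by their titles. Per the submitters' processing notes, the tools included STAR 2.7.9a, Picard 2.27.4, MACS2 2.2.7.1 and deepTools 3.5.1, and the genome build was mm39. The role of each tool, read shifting, the peak threshold and the way peaks were combined are not given in the sources used here.

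The analysis used a single consensus peak list for the whole series. It gives one set of values per peak and names no sample, group or replicate, so no comparison between genotypes or treatments was made and no replicate error could be given. The depth of each sample is unknown. The deposited score of a peak lay up to 1 below 10 times the deposited −log10 q. The deposited fold of a peak is the signal column of the narrowPeak layout, which MACS2 fills with enrichment over local background. These are the authors' values and were used only to describe, rank or filter peaks within the list. Coordinates are mm39 and were read as counted from 1 at the first base: neighbouring peaks never shared a base, and no summit offset reached the width under this reading, against 74 under a count from 0.

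Every deposited score was multiplied by whole numbers from 1 to 20, and the smallest multiplier that gave a whole number within 1e-06 was recorded. The scores were then modelled as means of 1 to 10 units, each unit being itself a mean of 2 whole numbers, plus a class of single whole numbers. A mean of 20 whole numbers needs the multiplier 20 in 40% of cases when its sum has no preferred remainder. Shares were estimated by expectation maximisation, with standard errors from a jackknife over 20 chromosomes. The share with all 10 units was the share of multiplier 20 divided by that 40%, with a Wilson 95% interval scaled alike. Intervals of medians are 95% order-statistic intervals. All intervals treat peaks as independent, and peaks are not biological replicates. On a simulated list of 140383 peaks, drawn from this same model with known shares close to those fitted, the largest error was 0.328 percentage points. That simulation checks the estimation and not whether the model holds.

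Peak density was the number of peaks divided by the distance from the first to the last peak of a chromosome. Spacing was compared with 100 random placements of the same widths along each chromosome, and with 100 placements within 1000000 bp windows, one-sided. Whether neighbouring peaks both had all 10 units was compared with 100 permutations within chromosomes, two-sided. That comparison was repeated within 20 bins of fold and within 20 bins of −log10 q. The 5 tests formed one family for Benjamini-Hochberg adjustment. On simulated lists, the placement test gave a permutation p = 0.248 for randomly placed peaks. The neighbour test, run on simulated lists with fewer permutations, gave a permutation p = 0.275 for permuted peaks. For runs of 5 peaks that shared their class it gave a permutation p = 0.0392, the smallest that this number of permutations allows. A peak was called outsized when its −log10 q was at least 20 times the median of its fold percentile. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

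The description of the catalogue and its 3 alternatives were fixed before the data were examined. The model of the scores, the density, spacing and neighbour comparisons and the rules for naming regions were chosen after the list was seen. The width test of single values in the closing observations replaced an earlier form after its outcome was seen. The earlier form took its edge from a percentile, so its written bound was certain to be met, and it also held an unwritten condition, on which it came out against the explanation. A comparison of peak number with gene number per chromosome was run and then left out, because the gene table belongs to another build, GRCm38.p6. For the same reason, planned results on promoters, gene lists, named genes and cell type markers were not analysed here, and planned motif results were not run because no genome sequence was used here.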

Results

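ATAC-seq was collected from bone marrow-derived macrophages with or without Smarca5, which encodes an ATPase of ISWI chromatin remodelling complexes. Cells were untreated or given the bacterial product LPS or the cytokine interferon beta for 1 or 2 h. The design asks how loss of the remodeller alters accessible chromatin before and after stimulation. The 19 samples fall into 10 groups, but the list analysed here gives one set of values per peak and names no sample, so effects of genotype and treatment could not be measured. The results below describe the regions in the list for the whole series. Their depth is unknown and no replicate error applies.

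The consensus list held 140383 peaks on 37 sequences of mm39 and covered 34.9 Mb. Of these, 137200 lay on the 19 autosomes, 3008 on X, 63 on Y and 112 on 16 sequences outside these assembled chromosomes. The list held 0 mitochondrial peaks. The median width was 196 bp, with quartiles of 153 and 299 bp and a range from 2 to 4526 bp. The authors' fold enrichment had a median of 9.85 (95% interval 9.82 to 9.89), with quartiles of 6.71 and 15.7. A fold of at least 20 was reached by 21075 peaks, whereas 14576 peaks, or 10.4% of the list, had a fold below 5. Across peaks, which are not independent replicates, fold and −log10 q had a Spearman's rho of 0.836.

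Accessible regions were unevenly spread over the chromosomes. Chromosome 11 was the densest, with 84.9 peaks per Mb, followed by chromosome 19 with 78.4 peaks per Mb. Chromosome 14 had the lowest autosomal density, 45.4 peaks per Mb, and the median autosome had 55.9 peaks per Mb. Chromosome X had 18.5 peaks per Mb, 0.330 times the autosomal median and below every autosome. The peaks on X were not of lower fold: their median was 10.3 (95% interval 9.94 to 10.5), against 9.59 to 10.1 over the autosomes. Of the 63 peaks on Y, 20 started within its first 5 Mb. Chromosome Y had 0.696 peaks per Mb, with a median fold of 7.45.

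**Figure D1:**
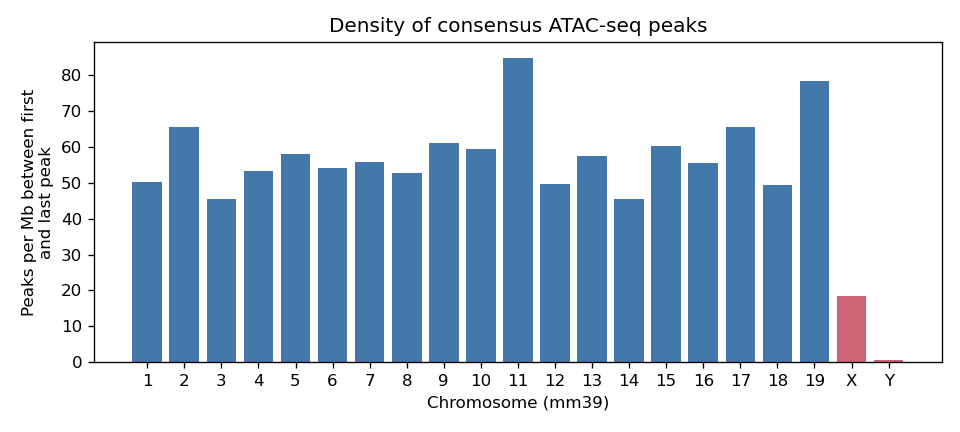
Bars give the number of consensus peaks per Mb (vertical axis) between the first and last peak of each mm39 chromosome (horizontal axis), autosomes in blue and X and Y in red. The autosomes lie between 45.4 and 84.9 peaks per Mb, and X lies at 18.5.

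Peaks lay in clusters. Among neighbouring peaks on the autosomes and X, 49.3% were within 5000 bp of each other. Random placement along each chromosome gave 26.0% (SD 0.101 over 100 placements; permutation p = 0.0099, the smallest they can give; adjusted p = 0.02 over 5 tests). Placement within windows of 1000000 bp gave 39.6% (permutation p = 0.0099, adjusted p = 0.02), so part of the difference from random placement lay in the uneven use of large domains. Random placement did not leave out gaps in the assembly. In windows of 50000 bp, 7.20% of windows held at least 10 peaks and 32.2% of all peaks, while 47.3% of windows held no peak. The densest window, chromosome 17 from 34300001 to 34350000, held 26 peaks with a median fold of 5.04. The windows on chromosome 2 from 83600001 to 83650000, chromosome 3 from 87400001 to 87450000 and chromosome 9 from 45150001 to 45200000 held 25 peaks each. Over the 10 densest windows, the median fold ranged from 4.01 to 7.80. Among the autosomes and X, the longest stretches without a peak were on X, from 23690072 to 33278980 (9.59 Mb) and from 59591229 to 67721853 (8.13 Mb). The longest on an autosome was on chromosome 14, from 106918932 to 115029011 (8.11 Mb).

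Most scores behaved as means of 2 or more whole numbers, while 24925 were already whole. Every score became whole under a multiplier of at most 20, and 0 peaks needed 11, 13, 15, 17 or 19. A model of 1 to 10 averaged units, each a mean of 2 whole numbers, plus single values, was fitted to the counts of multipliers. It requires equal counts for the multipliers 3 and 6, 5 and 10, 7 and 14, and 9 and 18, and these did not differ detectably (chi-square 0.684, 4 degrees of freedom, p = 0.953). The counts of the multipliers 1, 2, 4, 8, 12, 16 and 20 were matched by construction, so the fit did not test the shares taken from them. By this model, 36.6% of peaks were means over all 10 units (jackknife SE 0.478 percentage points over chromosomes; the 95% interval that treats peaks as independent, 36.1% to 37.1%, is narrower). Another 14.8% rested on 1 unit or a single value (jackknife SE 0.154 percentage points), and 48.6% on an intermediate number of units. Which samples make up a unit is not stated by the list.

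**Figure D2:**
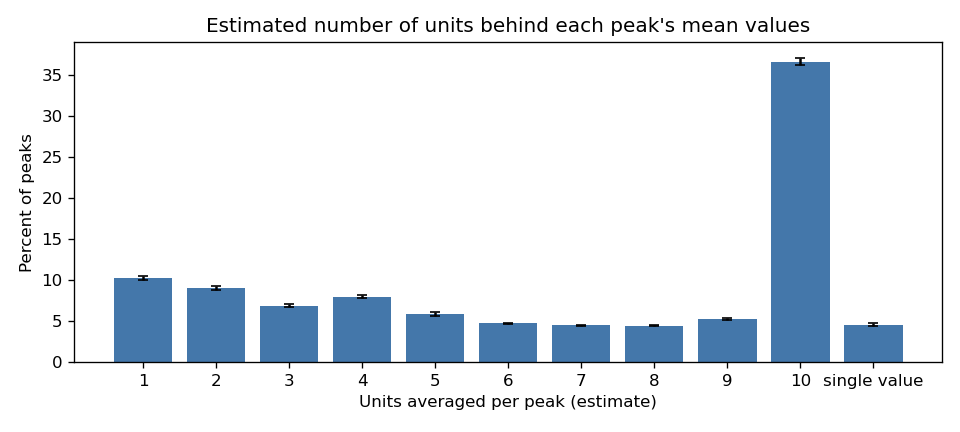
Bars give the estimated percent of peaks (vertical axis) by the number of units averaged in their values (horizontal axis), with a separate bar for single values; error bars are jackknife standard errors over chromosomes. The class of 10 units holds 36.6% of peaks, and no other class exceeds 10.2%.

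Stronger peaks were averaged over more units. In the lowest decile of peaks by fold, an estimated 3.22% (95% interval 2.79% to 3.72%) had all 10 units and 45.5% had 1 unit or a single value. In the highest decile, with folds from 23.1 to 75.7, 95.3% (95% interval 93.3% to 97.3%) had all 10 units and 0.0678% had 1 unit or a single value. The share with all 10 units was higher in each successive decile. If a unit enters a mean only where the peak passed a calling threshold there, such a rise would follow from the threshold. The way peaks were combined is not given, so the rise describes the list and is not independent evidence about the regions. Peaks of multiplier 20, which need all 10 units, had a median fold of 17.2 and a median width of 309 bp (95% interval 306 to 313). Peaks of multiplier 12, which need 6 units, had a median fold of 9.19 (95% interval 8.96 to 9.40) and a median width of 153 bp (95% interval 152 to 155). Width did not follow the number of units throughout: the median was 155 bp for 7 units, 158 bp for 8 and 166 bp for 9, but 183 bp for multiplier 1 or 2, a mixed class that takes in the peaks of 1 unit and part of every other class. The estimated share with all 10 units was 37.0% on X (95% interval 33.9% to 40.3%), within the autosomal range of 32.7% to 40.0%.

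**Figure D3:**
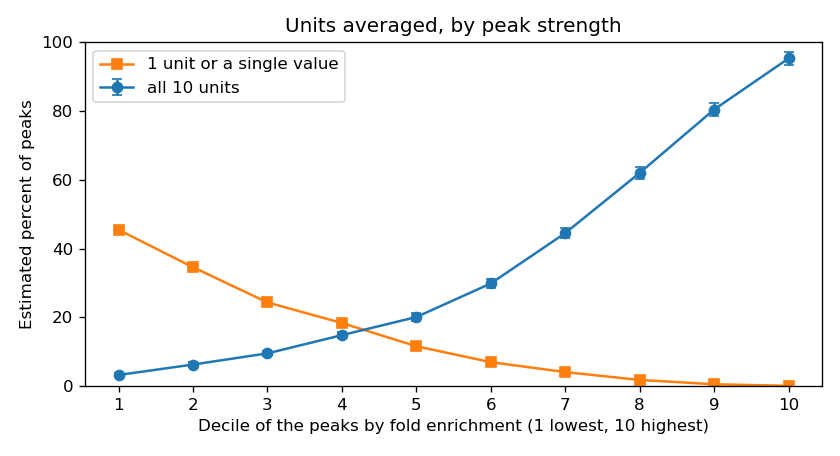
Points give the estimated percent of peaks (vertical axis) averaged over all 10 units, or resting on 1 unit or a single value, in each decile of the list by fold enrichment (horizontal axis), with 95% intervals for all 10 units. The share with all 10 units rises from 3.22% to 95.3%, and the share with 1 unit or a single value falls from 45.5% to 0.0678%.

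How often near neighbours both had all 10 units, relative to permuted peaks, depended on how strength was held fixed. Among 67413 pairs of separate peaks within 5000 bp, both peaks had all 10 units in an estimated 15.5%. Permutation within chromosomes gave 13.5% (two-sided permutation p = 0.02, adjusted p = 0.02), and permutation within bins of fold gave 9.35% (p = 0.02, adjusted p = 0.02). Permutation within bins of −log10 q gave 17.8%, above the observed share (p = 0.02, adjusted p = 0.02). The value 0.02 is the smallest that these permutations can give. The comparison therefore has no direction that holds for both measures of strength. The permutations drew on all peaks of a chromosome or bin, so the share with all 10 units among near peaks was not held fixed. A difference may reflect that share rather than likeness between neighbours.

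The regions with the most extreme values were named by rules chosen after the list was seen. The highest fold, 75.7, was at chromosome 2 from 69185883 to 69186009, a peak of 127 bp. Its multiplier was 1, so its score gives no evidence of more than a single value, and its −log10 q was 18.8 times the median of its fold percentile. The next were chromosome 6 from 9889952 to 9890155 with a fold of 74.1 and chromosome 6 from 103626031 to 103626248 with a fold of 72.3. Their −log10 q values were also high for their fold, at 9.68 and 14.7 times the median of their fold percentile. The highest −log10 q, 46003, was at chromosome 12 from 97028208 to 97028560, with a fold of 43.2. That −log10 q is 72.9 times the median of its fold percentile, which makes it one of the peaks called outsized. The widest peak, 4526 bp, was at chromosome 1 from 24650696 to 24655221, with a fold of only 3.59 and a −log10 q of 15623, which is 1054 times the median of its fold percentile. Among peaks of multiplier 20, 200 to 1000 bp wide and with a −log10 q under 5 times that median, the highest −log10 q was 2706, at chromosome 3 from 5925401 to 5925846, with a fold of 35.6. The next was 2449 at chromosome 2 from 172187201 to 172187684, with a fold of 37.2.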

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

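The tests in this part were chosen after the result was seen. The 112 peaks on 16 sequences outside the assembled chromosomes entered no comparison between chromosomes and drew attention for that reason. Some of these sequences carry a chromosome in their name, such as X_GL456233v2_random with 5 peaks, and were still kept apart from it. One such sequence, Un_JH584304v1, held 67 of these peaks, and Un_MU069435v1 held 14. The highest −log10 q among them was 17038, at Un_MU069435v1 from 30145 to 31125, with a fold of 28.8.

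In the whole list, 58 peaks had an outsized −log10 q for their fold, and 5 of them lay on these sequences. That is 4.46% of the peaks there, against 0.0378% on assembled chromosomes (odds ratio 124, two-sided Fisher's exact p = 1.31e-09). The test treats peaks as independent, although 67 of the 112 lie on a single sequence, so its p-value may overstate the evidence. Reads from sequence present in more copies than the assembly holds may contribute to these 5 peaks, since they raise coverage and local background together. The other peaks of this kind, on assembled chromosomes, were not examined by copy number. A second test, within 500 kb of each chromosome's first peak, found 0 of 746 peaks outsized. With 0.282 expected it was too small to inform. No biological explanation was tested.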

How the results depend on the processing

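The stricter threshold, merging and restriction to assembled chromosomes were planned for peak number, width and fold. Their use on other results, and all other alternatives, were chosen after seeing the data. Of 54 alternative values over 9 results, 36 stayed within their spread, on their side of the threshold or, for peak number, within 1.5 times, and 2 reversed. With only peaks at or above the median −log10 q, there were 70192 peaks with a median width of 248 bp and a median fold of 15.7. The share with all 10 units was then 67.3%, the share with 1 unit or a single value 1.68%, and the difference between the top and bottom decile by fold 59.5 points. These follow from removing weak peaks. Near neighbours both had all 10 units 0.908 times as often as permuted peaks there. In the full list, that ratio was 1.15 for permutation within chromosomes and 0.872 within bins of −log10 q. The cause was not tested. Merging touching peaks gave 198 bp and a fold of 9.90. Leaving them out gave 197 bp, a fold of 9.95 and 37.3% with all 10 units. Without candidates for single values, the values were 200 bp, a fold of 10.2, 38.5% with all 10 units and 10.3% with 1 unit or a single value, against 14.8% in the full list. Top and bottom deciles by −log10 q differed by 94.5 points. Spacing and X density kept their direction under every alternative run. Merged peaks have no mean of their own, so their units were not estimated. Other settings for promoters, gene lists, motifs and peaks per sample were not run. No paired analysis was possible because the list gives one value per peak over all samples. Unknown depth limits what the absence of a peak can show.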

Other observations

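The tests of the multipliers were chosen after the result was seen, and those of chromosome X were written before their values were seen, when the density ratio of 0.289 among peaks at or above the median −log10 q was already known. The first pattern is the set of whole-number multipliers. One mean over all libraries would give multipliers of 11, 13, 15, 17 or 19, and 0 peaks had one, which argues against one mean over all libraries. A candidate explanation is a mean over the 10 groups of group means, over 2 libraries in 9 groups and 1 library in the remaining group. Where touching peaks both had an unambiguous number of units, 99.2% of 265 pairs differed by exactly 1 unit, against 22.3% of 5057 separate pairs within 5000 bp. Pieces that end where one contributor's peak ends differ by 1 unit whatever the contributors are, so this value does not favour groups over other units. The link between units and the study's groups remains untested.

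Multiplier 1 was more frequent than multiplier 2, by 6376 peaks, as single values would give. Candidates for single values were chosen by a separate rule: multiplier 1, with fold, −log10 p and −log10 q all written in few digits. The 6991 candidates for single values were most often 117 bp wide and only 0.958% were narrower, against 24.5% narrower than the most frequent width among other peaks of multiplier 1 or 2. Such an edge is consistent with the minimum peak length of one library. This test replaced an earlier one after its outcome was seen: the earlier one came out against this explanation, on a condition not written down beforehand and with an edge that made its written bound certain to be met. One of the 10 groups has 1 sample, but no peak can be assigned to it from the list. If both readings hold, the share resting on 1 unit or a single value partly counts peaks from a group that needed no second library.

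The other pattern is the low density on X. At equal fold, −log10 q on X had a median of 0.874 relative to all peaks, below the lowest autosome at 0.924, so fewer reads per peak on X may play a part. Loss of weak peaks would leave strong peaks at a normal density, provided that fold on X is not itself lowered by fewer reads. Among peaks of fold 20 or more, however, the density on X was 0.359 times the autosomal median, close to the 0.330 of all peaks. Only on that condition, which was not tested, does this argue against loss of weak peaks as the whole cause. The sex of the animals was not used here and sequence was not tested. A comparison with gene number was run, but its gene table belongs to another build, so its outcome is not relied on and gene number remains open. No other biological explanation was tested.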
